A study of Arabidopsis thaliana with 24 samples.

How the data were processed

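The samples were 24 RNA sequencing libraries from 11-day-old seedlings grown on plates with 16 h of light at 23 °C and 8 h of dark at 22 °C. Per the labels, total RNA was sequenced either as 150-base paired reads or as 50-base single reads, without saying which library had which. Per the submitters' processing notes, the tools were HISAT2 2.2.0 and edgeR (no version given) with the genome build TAIR10. The read counter, the strand of the libraries and the filters are not stated. The authors deposited 3 tables of 32548 genes each, called sets 1 to 3 here, and the values in all 3 deposited tables are a normalised signal per gene. By their pattern these are pseudo-counts of edgeR, read counts that were adjusted by the authors to a common library size within each table. The values are not whole numbers and are not scaled for gene length. Of the 24 column names, 12 equal a sample title and 12 equal one with its slashes left out, and there were 0 columns without a sample.

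All 32548 identifiers were matched to the TAIR10.1 reference annotation, which keeps the sequence of TAIR10, so coordinates are given in it. Transposable element genes, planned as a further list, are not marked in that annotation and were not analysed. The size of 1 read in each column was estimated from the spacing of the low values. It was 0.962 to 1.044 in set 1, 0.901 to 1.065 in set 2 and 0.808 to 1.198 in set 3. The estimated depth was 18.8 to 19.0 M reads per library in set 1, 24.2 to 28.7 M in set 2 and 21.8 to 34.4 M in set 3. A value of 10 thus rests on about 10 reads, and fold changes of genes below that level are imprecise. Where a group was at 0 in both libraries, the fold is given as at least the ratio to a floor of 3 reads per library.

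The comparisons were set before the data were examined. Each mutant was compared with the Col-0 libraries of its own table, and further comparisons were made among genotypes of a table. The non-additive test took the effect of atx1/2/4/5 less those of atx1/2 and atx4/5, all against Col-0. Since the tables were normalised separately, atx4/5;jmj24 against atx4/5, jmj24/26/28 against jmj24 and the non-additive effect of atx4/5;jmj24 were not tested. The plan allowed for raw counts. The values are adjusted signal, so the test planned for normalised values was used. The planned models for raw counts, edgeR and DESeq2, do not apply and were not run.

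Values were taken as log2(value + 1), which understates the fold of genes with low levels. Genes with a value of at least 1 in at least 2 libraries of the set were kept, 22934, 23740 and 24843 genes in sets 1 to 3. Linear models with all groups of a table were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with empirical Bayes moderation, a mean-variance trend and the robust option. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. All adjusted p-values for genes are from this model and all those for lists are from camera. With 2 libraries against 2, the smallest 2-sided p of an exact permutation test is 0.333, so the tests rest on the spread pooled over groups and genes.

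Gene lists were written before the data were examined, from general knowledge of the species. The 20 lists cover COMPASS and related H3K4 methylation genes, the JMJ24 family and INO80, DNA methylation and demethylation machinery, genes silenced by DNA methylation, the FLC clade, flowering time promoters and floral identity, circadian clock, nuclear photosynthesis genes, heat shock response, DNA damage response, salicylic acid and immune response, jasmonate response, abscisic acid and drought response, auxin response and elongation growth, anthocyanin and flavonoid synthesis, glucosinolate synthesis, iron deficiency response, seed maturation and embryo program, root tissue markers and shoot meristem. 1 list entry had no value in the tables and was dropped. Lists were tested with camera in limma at an inter-gene correlation of 0.01, adjusted over the 20 lists of a comparison, and again with the correlation estimated per list. Each gene of a list was also adjusted over the list alone.

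The genes named were set by a rule written before the data were examined. For each mutant these were the genes targeted in it, FLC, FT and IBM1, and the 6 called genes with the largest rise and the 6 with the largest fall among those with a gene symbol, a mean of at least 2 in the higher group and both mutant libraries on the same side of both Col-0 libraries. Up to 3 called members by adjusted p were added from each of the 5 lists with the smallest camera p among lists with a called member. In the other comparisons the 3 largest in each direction were named. ATX4 and ATX5 in ino80 and jmj24, the genes called in 8 comparisons and those named only in the closing section were chosen after their values were seen. Overlaps were set against independent lists and against 20 simulated tables in which no group differed but Col-0 libraries were shared as in the data.

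The pipeline was tested on simulated data made from the tables, with 200 genes of a mean of at least 10 changed 1.5-fold, 2-fold or 4-fold. Of the 2-fold changes it recovered 85.1% for ino80, 79.1% for jmj24, 77.6% for atx1/2, 89.6% for atx1/2/4/5 against atx2/3/4/5 and 64.2% for the non-additive effect. Of the 1.5-fold changes it recovered 71.6%, 44.8%, 65.7%, 67.2% and 38.8%. False calls made up 11.1%, 17%, 7.51%, 10.8% and 6.47% of calls, above the nominal 5%, so gene counts hold more of them than stated. In 3 of these comparisons camera called the 1 raised list alone. This does not show how it treats lists of correlated genes.

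The alternatives tried were quantile normalization, limma without a trend, no filter on low values, a pseudocount of 0.1, only the groups compared in the fit, the replicate number as a block, and leaving out each library in turn. For lists they were an estimated correlation and fry, and for overlaps an adjusted p under 0.01. Column totals set equal within a table, quantile normalization for the lists, and the fit of ATX1 in atx1/2 without replicate 1 of atx1/2/4/5 were chosen after seeing the data.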

Results

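Gene expression was measured by RNA sequencing in 24 libraries of 11-day-old Arabidopsis thaliana seedlings, grown on plates under long days. Col-0, the wild-type accession, had 6 libraries, and each of 9 other genotypes had 2. The series concerns COMPASS, the group of complexes that methylate lysine 4 of histone H3. The labels name mutants of the ATX histone methyltransferase genes (ATX1 to ATX5), of the JmjC-domain genes JMJ24, JMJ26 and JMJ28 and of the chromatin remodeller INO80, and an RNAi line against WDR5A, a core COMPASS subunit. The question the series title gives is how far COMPASS complexes act redundantly on gene expression and DNA methylation, and only expression was measured here. The libraries came in 3 sets, 1 deposited table each, with separate normalisation and separate Col-0 libraries. Set 1 held Col-0 and ino80, set 2 held Col-0, jmj24 and atx4/5;jmj24, and set 3 held Col-0, atx1/2, atx4/5, atx1/2/4/5, atx2/3/4/5, jmj24/26/28 and WDR5A_RNAi. The estimated depth was 18.8 to 34.4 M reads per library. Values below are normalised read counts, as mean ± SD of the 2 libraries of each group (n = 2) with the mutant first, and fold changes are on the scale log2(value + 1) with their standard errors from limma. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Between replicates the Pearson correlation over genes was 0.986 to 0.990. In set 3, the first principal component held 49.2% of the variance and set the atx1/2/4/5 and atx2/3/4/5 libraries apart from the other 10.

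**Figure D1:**
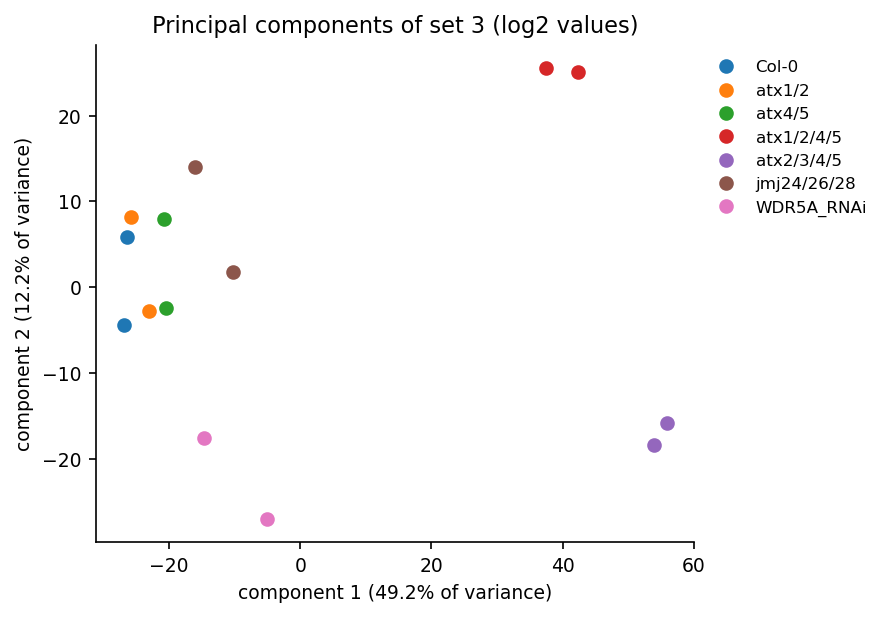
The first (horizontal) and second (vertical) principal components of the log2 values of the 14 libraries of set 3 over 18624 genes, 1 point per library, coloured by group. The 4 libraries of atx1/2/4/5 and atx2/3/4/5 lie between 37.5 and 55.9 on component 1, and the other 10 libraries lie below 0.

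The genes named in the genotypes were examined first, since they check the labels. INO80 (AT3G57300, chromosome 3, 21199150 to 21207893 in the TAIR10.1 annotation) fell in ino80 to 875 ± 24.2 against 1749 ± 68.9 (log2 fold change -0.998 ± 0.06, adjusted p = 1.75e-05). JMJ24 (AT1G09060, chromosome 1, 2921064 to 2925826) fell in jmj24 to 299 ± 31.6 against 1466 ± 70.5 (log2 fold change -2.29 ± 0.10, adjusted p = 8.22e-07). It fell by a similar amount in atx4/5;jmj24 (log2 fold change -2.42 ± 0.10) and jmj24/26/28 (log2 fold change -2.58 ± 0.07). In jmj24/26/28, JMJ26 (AT1G11950, chromosome 1, 4034479 to 4039065) was at 0.496 ± 0.701 against 164 ± 16.6, and JMJ28 (AT4G21430, chromosome 4, 11407804 to 11412279) fell to 293 ± 28.4 against 576 ± 28.3 (log2 fold change -0.98 ± 0.13, adjusted p = 3.53e-04). ATX4 (AT4G27910, chromosome 4, 13893915 to 13900630) fell in all 4 genotypes named for it, to 43 ± 10.9 in atx4/5, 29.5 ± 11.8 in atx1/2/4/5 and 42.7 ± 1.18 in atx2/3/4/5 against 500.2 ± 3.3 in Col-0, and to 129 ± 21.5 against 474 ± 30.9 in atx4/5;jmj24. ATX5 (AT5G53430, chromosome 5, 21677146 to 21684122) fell in atx4/5 (log2 fold change -1.14 ± 0.14), atx1/2/4/5 (log2 fold change -3.73 ± 0.14) and atx2/3/4/5 (log2 fold change -2.20 ± 0.14). In atx4/5;jmj24 it was at 578 ± 85.1 against 455 ± 30.0, a difference that did not pass the test (adjusted p = 0.0701). Against jmj24 of the same set, where ATX5 was at 816, it was lower in both atx4/5;jmj24 libraries without passing the test (log2 fold change -0.51 ± 0.10, adjusted p = 0.051).

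Several of the targeted genes were higher or did not pass the test for a fall. WDR5A (AT3G49660, chromosome 3, 18413564 to 18415713) was higher in the libraries labelled WDR5A_RNAi, at 918 ± 67 against 100.1 ± 18.7 (log2 fold change 3.19 ± 0.18, adjusted p = 3.24e-07). ATX3 (AT3G61740, chromosome 3, 22850811 to 22857016) was higher in the libraries labelled atx2/3/4/5, at 690.2 ± 71.1 against 386 ± 3.17 (log2 fold change 0.83 ± 0.10, adjusted p = 7.67e-06). ATX2 (AT1G05830, chromosome 1, 1754130 to 1761909) lay between 1315 and 1365 in the 3 genotypes named for it and at 1333 ± 85.1 in Col-0. None of the differences passed the test. ATX1 (AT2G31650, chromosome 2, 13455272 to 13462431) was lower in both atx1/2 libraries than in both Col-0 libraries, at 181 ± 0.346 against 258 ± 1.18, but was not called (log2 fold change -0.51 ± 0.40, adjusted p = 0.921). That standard error reflects the atx1/2/4/5 libraries, in which ATX1 was at 568 in replicate 1 and 191 in replicate 2. With replicate 1 of atx1/2/4/5 left out of the fit, the change in atx1/2 was -0.51 ± 0.12 (adjusted p = 0.11), and with only the 2 groups fitted its adjusted p was 0.344. In atx1/2/4/5 itself ATX1 was not called (adjusted p = 0.56), but it was called lower without replicate 1 (adjusted p = 0.0366) and higher without replicate 2 (adjusted p = 4.73e-05). A value per gene counts reads from any part of the gene, so it cannot tell full transcripts from transcripts that end at an insertion or from those of an RNAi construct. Directions for these lines are therefore given for the libraries as labelled.

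**Figure D2:**
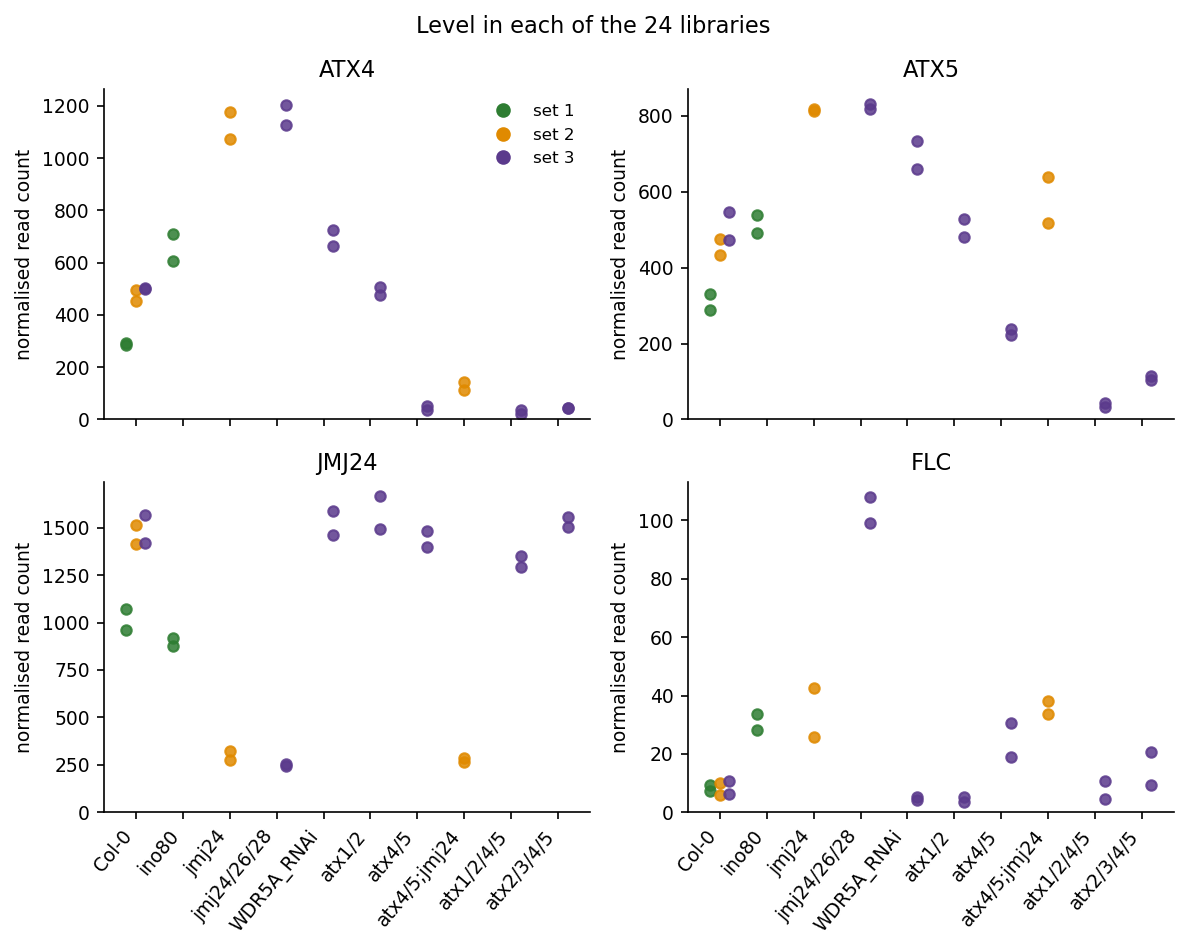
Normalised read counts (vertical axes, from 0) of ATX4, ATX5, JMJ24 and FLC in each of the 24 libraries, 1 point per library, by genotype (horizontal axes) and coloured by set. ATX4 lies at 1165 on average in jmj24/26/28 and at 500.2 in the Col-0 libraries of the same set.

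The ino80 comparison asks which transcripts depend on the INO80 chromatin remodeller. The nuclear photosynthesis list was called lower in ino80, with 18 of 21 genes down. The heat shock, anthocyanin and seed maturation lists were called higher, with 8 of 18, 6 of 12 and 4 of 14 genes up, and all 4 list calls were lost with an estimated correlation (adjusted p = 0.682). LHCB1.2, a light-harvesting protein of photosystem II, fell to 55715 ± 525 against 99528 ± 8889 (log2 fold change -0.83 ± 0.07), and PSAD1 of photosystem I fell to 42648 ± 1304 against 62051 ± 1621 (log2 fold change -0.54 ± 0.05). The flowering repressor FLC (AT5G10140, chromosome 5, 3173382 to 3179448) rose to 31 ± 3.9 against 8.26 ± 1.32 (log2 fold change 1.79 ± 0.33, adjusted p = 0.00426). Its relative MAF5 (AT5G65080) rose to 243 ± 7.6 against 20.7 ± 4.61 (log2 fold change 3.51 ± 0.20, adjusted p = 9.95e-06). Among the largest rises was that of SYN1 (AT5G05490), a meiotic cohesin subunit, to 139 ± 19.1 against 3.62 ± 0.772 (log2 fold change 4.93 ± 0.29, adjusted p = 1.14e-05). Among the largest falls were those of HDA2 (AT5G26040), a histone deacetylase, to 1.45 ± 0.682 against 100.2 ± 5.77 (log2 fold change -5.40 ± 0.36) and ACR1 (AT5G65890) to 28.1 ± 1.15 against 397 ± 15.1 (log2 fold change -3.78 ± 0.15). QQS (AT3G30720), a gene acting on starch content, fell to 9.67 ± 8.26 against 399 ± 88.8 (log2 fold change -5.47 ± 0.76, adjusted p = 0.0314).

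By list, 18 of the 21 measured nuclear photosynthesis genes fell in ino80 and none rose, with 18 lower when adjusted over the list alone (camera, adjusted p = 1.39e-08, adjusted p = 0.682 with an estimated correlation). 8 of 18 heat shock genes rose, 8 adjusted over the list alone (adjusted p = 4.54e-05, adjusted p = 0.682 with an estimated correlation). Among them the chaperone HSP70 rose to 1646 ± 33 against 973 ± 51.1, and the chloroplast protein HSP21 rose to 33.4 ± 11.5 against 1.55 ± 0.696. 6 of 12 anthocyanin and flavonoid genes rose, 9 adjusted over the list alone (adjusted p = 9.28e-04, adjusted p = 0.682 with an estimated correlation). DFR was at 649 ± 50.1 against 419.5 ± 45.3 and the regulator TT8 at 57.2 ± 13 against 24.8 ± 1.79. Of 14 measured seed maturation genes 4 rose, 4 adjusted over the list alone (adjusted p = 0.0147, adjusted p = 0.682 with an estimated correlation). OLEO1 and TIP3;1 were at 0 in both Col-0 libraries of the set and at 21.8 ± 24.1 and 13.1 ± 11.7 in ino80. These means were at least 7.02-fold and 4.21-fold higher than a floor of 3 reads per library. With SDs near or above the means, the 2 ino80 libraries differed widely, and the folds do not hold for each of them. In the iron deficiency list 5 of 16 genes fell and 1 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.015, adjusted p = 0.682 with an estimated correlation). BHLH101, a regulator of the response, fell to 3.87 ± 1.42 against 63.4 ± 22.9 and the peptide gene IMA3 to 74 ± 12.5 against 353 ± 87.2. Root markers rose in 8 and fell in 2 of 17 cases (adjusted p = 0.015, adjusted p = 0.682 with an estimated correlation). Smaller calls were made for the glucosinolate list (3 up of 15, adjusted p = 0.0295, adjusted p = 0.759 with an estimated correlation) and the DNA damage list (2 up of 11, adjusted p = 0.0491, adjusted p = 0.682 with an estimated correlation). The auxin list was called lower (2 up and 3 down of 19, adjusted p = 0.0491, adjusted p = 0.746 with an estimated correlation). The JMJ24 family list, which holds INO80 itself, had 3 of 7 members lower (adjusted p = 0.0295, adjusted p = 0.682 with an estimated correlation). The seed, glucosinolate, DNA damage, auxin and JMJ24 family calls were each lost without at least 1 library. In all, limma called 2451 genes higher and 2684 lower among 22934 tested, of which 387 and 429 changed at least 2-fold. With column totals set equal, a scaling chosen after seeing the data, 4114 were higher and 1916 lower. The total of 5135 fell to 400 without ino80 replicate 1, 601 without ino80 replicate 2, 3029 without Col-0 replicate 6, 3206 without Col-0 replicate 5 and 581 without a mean-variance trend. 9 of the 26 called genes named by the rule kept their call without any 1 library. These were INO80, SYN1, MAF5, HDA2, ACR1 and, lost without a trend, QQS, CYP81D3, HSP70 and IMA3.

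Loss of the JmjC-domain protein JMJ24 was examined in jmj24. The DNA damage, glucosinolate, root and seed lists were called higher, with 5 of 11, 6 of 15, 3 of 17 and 2 of 17 genes up, and these calls were lost with an estimated correlation (adjusted p = 0.15). PARP2, a DNA strand-break sensor, rose to 605 ± 8.05 against 251 ± 25.4 (log2 fold change 1.27 ± 0.11, adjusted p = 1.01e-04), and TSO2, a ribonucleotide reductase subunit, rose to 2166 ± 84.9 against 1399 ± 18.8 (log2 fold change 0.63 ± 0.06). ATX4 rose to 1124 ± 72.5 against 474 ± 30.9 (log2 fold change 1.25 ± 0.12, adjusted p = 2.52e-04) and ATX5 to 816 ± 4.29 against 455 ± 30.0 (log2 fold change 0.84 ± 0.10, adjusted p = 0.00115), and both calls were lost without a mean-variance trend (adjusted p = 0.108 and 0.153). FLC rose to 34.1 ± 11.8 against 8.03 ± 2.79 (log2 fold change 1.95 ± 0.40, adjusted p = 0.023). Among the largest falls were those of QQS to 28 ± 2.42 against 721 ± 96.4 (log2 fold change -4.63 ± 0.22) and PCC1 (AT3G22231), a pathogen-responsive gene, to 241 ± 37.6 against 2783 ± 107 (log2 fold change -3.53 ± 0.11, adjusted p = 8.22e-07). NIMIN1, which encodes a partner of the salicylic acid receptor NPR1, fell to 3.63 ± 0.593 against 32 ± 4.64. Seed genes were at 0 in both Col-0 libraries of the set and present in jmj24. M17 was at 26.8 ± 15, OLEO2 at 19.2 ± 4.39 and TIP3;1 at 20.1 ± 10.1, at least 9.37-fold, 6.69-fold and 7.03-fold higher.

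In jmj24, 5 of 11 DNA damage genes rose, 7 adjusted over the list alone (camera, adjusted p = 1.95e-06, adjusted p = 0.15 with an estimated correlation). 6 of 15 glucosinolate genes rose, 8 adjusted over the list alone (adjusted p = 1.81e-05, adjusted p = 0.15 with an estimated correlation). FMOGSOX1 of that list was at 400.1 ± 4.52 against 248 ± 16.3. 3 of 17 root markers rose, 5 adjusted over the list alone (adjusted p = 9.37e-05, adjusted p = 0.15 with an estimated correlation). PRP3 was at 785 ± 17.3 against 535 ± 10.6 and the phosphate transporter PHT1;1 at 3729 ± 181 against 2982 ± 102. 2 of 17 seed maturation genes rose, 5 adjusted over the list alone (adjusted p = 8.37e-05, adjusted p = 0.15 with an estimated correlation). The jasmonate list was called higher with 1 of 19 members past the threshold, AOS at 4669 ± 289.6 against 3118 ± 122 (adjusted p = 1.96e-05, adjusted p = 0.434 with an estimated correlation). The photosynthesis list (1 of 21 lower, adjusted p = 0.0017, adjusted p = 0.434 with an estimated correlation) and the salicylic acid list (2 of 24 lower, adjusted p = 0.00177, adjusted p = 0.526 with an estimated correlation) were called lower. The photosynthesis call was lost with quantile normalization (adjusted p = 0.0619) and without jmj24 replicate 2 (adjusted p = 0.0802), and the salicylic acid call was lost without Col-0 replicate 4. In limma 330 genes higher and 339 lower among 23740 tested were called, 61 and 103 of them at least 2-fold. The total of 669 fell without any 1 library, most without jmj24 replicate 1. Without a mean-variance trend it was 77, and 28 of these were among the 669. 6 of the 24 called genes named by the rule kept their call without any 1 library. They were JMJ24, QQS, PCC1, PARP2 and, lost without a trend, TSO2 and AOS.

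The jmj24/26/28 libraries are labelled as mutant in 3 related JmjC-domain genes. FLC was among the largest rises, at 104 ± 6.19 against 8.46 ± 3.26 (log2 fold change 3.51 ± 0.48, adjusted p = 4.5e-04). ATX4 rose to 1165 ± 56.1 against 500.2 ± 3.3 (log2 fold change 1.22 ± 0.21, adjusted p = 0.00408) and ATX5 to 824 ± 8.06 against 509 ± 52.9 (log2 fold change 0.70 ± 0.14, adjusted p = 0.00865). The ATX5 call was lost without Col-0 replicate 1 or either jmj24/26/28 library, and both calls were lost without a mean-variance trend (adjusted p = 0.0521 and 0.0546). GASA3 (AT4G09600) and PCR1 (AT1G14880) rose to 41 ± 13.2 against 3 ± 0.0986 and 60.2 ± 4.04 against 6.46 ± 3.32. The largest falls included those of 4 receptor-like kinase genes that lie side by side next to JMJ28 on chromosome 4, between 11388827 and 11405235 in TAIR10.1. CRK29, CRK28, B120 and RK3 were at 0 in both libraries against 819 ± 29, 275 ± 27.2, 176 ± 12 and 90.8 ± 2.74 in Col-0, at least 300-fold, 101-fold, 64.6-fold and 33.3-fold lower than a floor of 3 reads per library. CRK28 and CRK29 overlap in the annotation, so reads in the overlap cannot be assigned to one of them. QQS was at 0.496 ± 0.701 against 46.3 ± 13.4 (log2 fold change -5.04 ± 0.47) and MAP1B (AT3G25740) at 22.6 ± 12.4 against 395 ± 36.6 (log2 fold change -4.17 ± 0.33, adjusted p = 1.75e-05).

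Of the lists, the jasmonate genes rose in jmj24/26/28 in 5 of 19 cases, 7 adjusted over the list alone (camera, adjusted p = 4.43e-05, adjusted p = 0.202 with an estimated correlation). The storage protein VSP2 was at 12176 ± 818 against 7273 ± 229 and the synthesis gene AOC2 at 5812 ± 872 against 3172 ± 396. In the salicylic acid and immune list 2 genes rose and 1 fell of 24 (adjusted p = 1.99e-04, adjusted p = 0.202 with an estimated correlation). PR2 was at 192 ± 26 against 60.7 ± 22.1 and PBS3 at 35.9 ± 4.59 against 95.5 ± 13.7. 2 of 17 iron deficiency genes fell, 4 adjusted over the list alone (adjusted p = 5.06e-04, adjusted p = 0.319 with an estimated correlation). FRO3 was at 792 ± 5.82 against 1424 ± 217 and the iron transporter IRT1 at 513 ± 48.5 against 1051 ± 265. The COMPASS list was called higher, with ATX4 and ATX5 as its called members (2 of 11 up, adjusted p = 5.82e-04, adjusted p = 0.147 with an estimated correlation), and the JMJ24 family list lower, with its 3 mutated members called (adjusted p = 1.99e-04, adjusted p = 0.147 with an estimated correlation). The FLC clade was called higher with FLC as its 1 called member of 6 (adjusted p = 0.0366, adjusted p = 0.202 with an estimated correlation). Seed maturation genes were called higher with 1 of 20 past the threshold and 7 adjusted over the list alone (adjusted p = 0.00143, adjusted p = 0.296 with an estimated correlation). Abscisic acid genes were called higher with 1 of 25 (adjusted p = 0.0058, adjusted p = 0.589 with an estimated correlation), and photosynthesis genes lower with 1 of 21 (adjusted p = 0.00248, adjusted p = 0.589 with an estimated correlation). The last call was lost with quantile normalization (adjusted p = 0.902), and it and the abscisic acid and FLC clade calls were each lost without at least 1 library. In total 314 genes higher and 642 lower among 24843 tested were called, 88 and 289 at least 2-fold. The 956 calls became 396 without Col-0 replicate 1, 407 without jmj24/26/28 replicate 2, 473 without jmj24/26/28 replicate 1 and 476 without a mean-variance trend. The calls of OLEO1, ATPXG2, PBS3, PR5, IRT1 and ATX5 were each lost without at least 1 library, and 19 of the 25 called genes named by the rule kept theirs. The difference between jmj24/26/28 and jmj24 was not tested, since the sets were normalised separately.

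**Figure D3:**
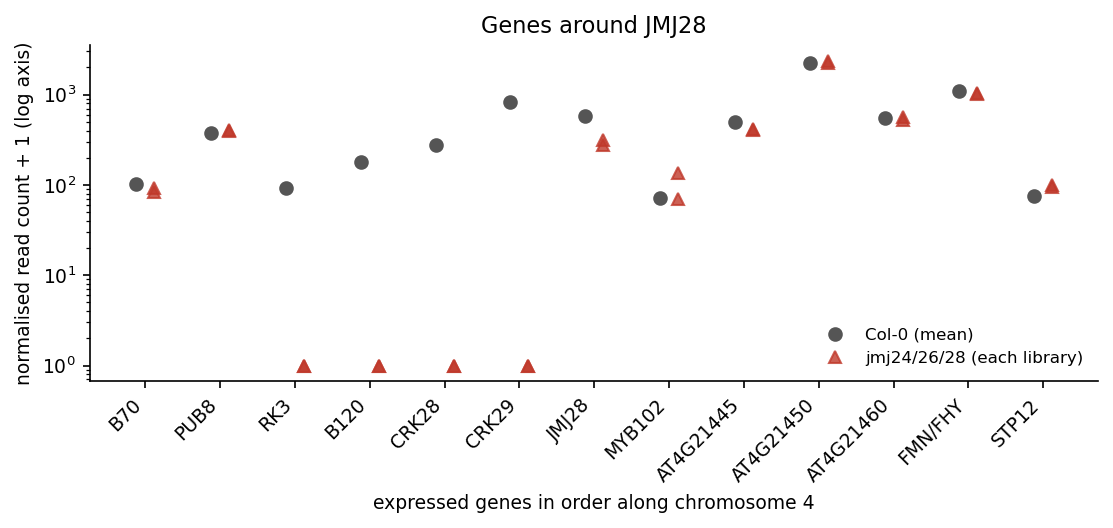
Normalised read count + 1 (vertical log axis) of the expressed genes around JMJ28 in their order along chromosome 4 (horizontal axis), with the Col-0 mean as a circle and each jmj24/26/28 library as a triangle. RK3, B120, CRK28 and CRK29 are at 0 reads in both jmj24/26/28 libraries, JMJ28 is at 293 against 576, and the genes on either side lie near their Col-0 levels.

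The libraries labelled WDR5A_RNAi, in which WDR5A itself was higher, had the abscisic acid and salicylic acid lists called higher than in Col-0, with 6 of 25 and 5 of 24 genes up. The auxin, iron and photosynthesis lists were called lower, with 6 of 19, 7 of 17 and 7 of 21 genes down. With an estimated correlation these 5 calls were lost (adjusted p = 0.167 to 0.541). The pathogenesis gene PR1 rose to 242 ± 79.8 against 7.94 ± 5.4 (log2 fold change 4.87 ± 0.85, adjusted p = 0.0128) and the defensin gene PDF1.2A to 81 ± 12.2 against 2.51 ± 2.2 (log2 fold change 4.69 ± 0.58, adjusted p = 0.00158). The endoplasmic reticulum chaperone gene BIP3 rose to 161 ± 18.3 against 10.5 ± 2.46 (log2 fold change 3.83 ± 0.33, adjusted p = 1.06e-05). CRK38 and NAC085 were at 0 in Col-0 and at 12.3 ± 1.28 and 10.9 ± 0.936 here, at least 4.12-fold and 3.62-fold higher. MGDC (AT2G11810), a galactolipid synthase, fell to 109 ± 37.6 against 497 ± 9.54 (log2 fold change -2.22 ± 0.25, adjusted p = 4.64e-04). 6 of 25 abscisic acid and drought genes rose, 13 adjusted over the list alone (camera, adjusted p = 4.07e-11, adjusted p = 0.336 with an estimated correlation). RAB18 was at 2395 ± 660.4 against 948 ± 102 and RD29B at 3740.4 ± 2954 against 352 ± 219. The calls of these 2 genes and of ABI2, the named members of the list, were lost with only the 2 groups fitted. 6 of 19 auxin and elongation genes fell, 12 adjusted over the list alone (adjusted p = 6.81e-07, adjusted p = 0.167 with an estimated correlation). IAA3 was at 711 ± 95.8 against 1187 ± 22.7. 7 of 17 iron deficiency genes fell, 12 adjusted over the list alone (adjusted p = 2.14e-06, adjusted p = 0.336 with an estimated correlation). BHLH101 was at 41.4 ± 8.07 against 111 ± 1.38 and FIT at 183 ± 13.2 against 277 ± 2.41. 7 of 21 photosynthesis genes fell, 12 adjusted over the list alone (adjusted p = 3.62e-05, adjusted p = 0.541 with an estimated correlation). RBCS3B was at 141537 ± 9394 against 193094 ± 15318, and both its call and that of the list (adjusted p = 0.496) were lost with quantile normalization.

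In the same libraries labelled WDR5A_RNAi the COMPASS list was called higher with 3 of 11 members up (camera, adjusted p = 8.87e-04, adjusted p = 0.167 with an estimated correlation). These were WDR5A itself, ATX3 at 581 ± 55.3 against 386 ± 3.17 and ATX5 at 697 ± 51.4 against 509 ± 52.9, and the ATX5 call was lost without any 1 of the 4 libraries. The salicylic acid list (5 of 24 up, adjusted p = 0.00416, adjusted p = 0.373 with an estimated correlation) and the jasmonate list (5 up and 1 down of 19, adjusted p = 0.00416, adjusted p = 0.481 with an estimated correlation) were called higher. So were the anthocyanin list (2 of 11 up, adjusted p = 0.00118, adjusted p = 0.481 with an estimated correlation) and the glucosinolate list (2 of 15 up, adjusted p = 0.0317, adjusted p = 0.556 with an estimated correlation). Root markers were called lower as a list although none of the 17 passed the threshold alone (adjusted p = 0.0018, adjusted p = 0.336 with an estimated correlation). The jasmonate, glucosinolate and root calls were each lost without at least 1 library. Limma called 1124 genes higher and 1250 lower among 24843 tested, with 195 and 219 at least 2-fold. The total of 2374 was 710 without WDR5A_RNAi replicate 2, 1007 without Col-0 replicate 1, 1518 without Col-0 replicate 2, 1222 with only the 2 groups fitted and 1233 without a mean-variance trend. 12 of the 27 called genes named by the rule kept their call whichever library was left out (WDR5A, PDF1.2A, MIR5020b, BIP3, CRK38, NAC085, MGDC, RAB18, IAA3, BHLH101, RBCS3B, ATX3).

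Redundancy among the ATX genes was addressed with 4 combinations, beginning with atx1/2. Few transcripts differed between the libraries labelled atx1/2 and Col-0, with 20 genes higher and 50 lower among 24843 tested and 1747 genes at an unadjusted p under 0.05. SK4 (AT1G20140), a SKP1-like gene, fell to 31.6 ± 2.32 against 185 ± 4.5 (log2 fold change -2.51 ± 0.17, adjusted p = 1.49e-06), and it alone of the 13 called genes named by the rule kept its call whichever library was left out. The myosin genes XIC and XIE fell, XIC to 8.62 ± 3.31 against 47.4 ± 2.23 (log2 fold change -2.37 ± 0.38) and XIE to 0 against 8.47 ± 1.85, at least 2.63-fold lower. MEE29 (AT2G35340) fell to 88.3 ± 13.2 against 236 ± 23.5 and DELTA-VPE (AT3G20210) to 9.06 ± 4.75 against 35.9 ± 0.26. GMI1, a DNA damage gene, fell to 72.1 ± 13.5 against 165 ± 33.6 (log2 fold change -1.18 ± 0.21, adjusted p = 0.0246). Among the largest rises were those of genes with low levels, AT3G29633 at 13.9 ± 2.34 against 0.998 ± 0.0347 and AT1G48400 at 28.4 ± 5.41 against 4.48 ± 1.97. List calls were made for heat shock genes (higher, 0 of 18 past the threshold, camera, adjusted p = 0.00362, adjusted p = 0.508 with an estimated correlation), DNA damage genes (lower, 1 of 11, adjusted p = 0.0144, adjusted p = 0.508 with an estimated correlation) and DNA methylation machinery (lower, 0 of 39, adjusted p = 0.0144, adjusted p = 0.508 with an estimated correlation). The number of called genes was 18 without Col-0 replicate 1, 44 without Col-0 replicate 2, 32 without atx1/2 replicate 1, 27 without atx1/2 replicate 2 and 33 with only the 2 groups fitted. Without a mean-variance trend 30 were higher and 45 lower. The 3 list calls were each lost without at least 1 library.

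In atx4/5, falls outnumbered rises, with 239 genes higher and 565 lower among 24843 tested. HOL2 (AT2G43920), a methyltransferase gene, fell to 26.4 ± 12.7 against 526 ± 3.66 (log2 fold change -4.34 ± 0.34, adjusted p = 2.69e-05) and QQS to 2.37 ± 0.0425 against 46.3 ± 13.4 (log2 fold change -3.78 ± 0.47). The sugar transporter gene STP11 fell to 0.581 ± 0.786 against 17.9 ± 3.66 (log2 fold change -3.66 ± 0.47) and the homeobox gene ATHB54 to 2.96 ± 0.719 against 39.5 ± 4.8 (log2 fold change -3.36 ± 0.52). The MADS-box genes AGL72 and SHP1 rose, AGL72 from 0 in both Col-0 libraries to 11.8 ± 2.88, at least 3.93-fold, and SHP1 to 24.8 ± 5.08 against 4.48 ± 1.97 (log2 fold change 2.27 ± 0.39, adjusted p = 0.0037). The jasmonate list was called higher, with 4 of 19 members up and 6 adjusted over the list alone (camera, adjusted p = 0.0212, adjusted p = 0.737 with an estimated correlation). VSP2 was at 12089 ± 400.2 against 7273 ± 229 and AOC2 at 5856 ± 24 against 3172 ± 396. The iron list was called lower with 1 of 17 down, FRO3 at 829 ± 43.2 against 1424 ± 217 (adjusted p = 0.0375, adjusted p = 0.737 with an estimated correlation). The glucosinolate list was called higher with 0 of 15 past the threshold (adjusted p = 0.0375, adjusted p = 0.737 with an estimated correlation). Each of these 3 list calls was lost without at least 1 library. The auxin-conjugating enzyme gene GH3.5 fell to 811 ± 34.6 against 1543 ± 301 (log2 fold change -0.91 ± 0.12). The 804 calls, 38 up and 301 down at least 2-fold, became 361 without atx4/5 replicate 2, 386 without Col-0 replicate 2, 395 without Col-0 replicate 1, 455 without atx4/5 replicate 1, 416 without a mean-variance trend and 468 with only the 2 groups fitted. 14 of the 20 called genes named by the rule kept their call whichever library was left out, and CYP77A9, MIR395e, TPS03, SHP1, MYB27 and MIR841b did not.

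The atx4/5;jmj24 libraries, in which ATX5 was not lower than in Col-0, had the photosynthesis list called lower and the glucosinolate, jasmonate and flavonoid lists called higher. In the last 3 lists 7 of 15, 4 of 19 and 4 of 11 members rose, and all 4 calls were lost with an estimated correlation (adjusted p = 0.281 to 0.663). 15 of 21 nuclear photosynthesis genes fell, 21 adjusted over the list alone (camera, adjusted p = 1.63e-15, adjusted p = 0.281 with an estimated correlation). LHCA3 was at 17501 ± 268 against 25309 ± 1107 and PSAD1 at 23505 ± 332 against 31847 ± 36.3. 7 of 15 glucosinolate genes rose and 1 fell, 10 and 1 adjusted over the list alone (adjusted p = 1.1e-04, adjusted p = 0.281 with an estimated correlation). BCAT4 was at 3709 ± 42 against 2439.9 ± 300.3. 4 of 19 jasmonate genes rose, 4 adjusted over the list alone (adjusted p = 1.37e-04, adjusted p = 0.663 with an estimated correlation). AOS was at 5391 ± 501 against 3118 ± 122. 4 of 11 flavonoid genes rose, 7 adjusted over the list alone (adjusted p = 0.00119, adjusted p = 0.281 with an estimated correlation). Chalcone synthase CHS was at 8281 ± 183 against 5973 ± 591. Iron genes fell in 2 of 16 cases (adjusted p = 8.07e-04, adjusted p = 0.695 with an estimated correlation), a list call lost without atx4/5;jmj24 replicate 1. HOL2 fell to 15.6 ± 7.66 against 351 ± 46 (log2 fold change -4.48 ± 0.29, adjusted p = 1.53e-05), TRFL8 (AT2G37025) to 5.56 ± 0.768 against 93.4 ± 32.2 and the amylase gene BAM6 to 16.2 ± 7.28 against 197 ± 71.4. SHP1 rose to 57 ± 10.1 against 9.01 ± 1.33 (log2 fold change 2.53 ± 0.36, adjusted p = 0.00123) and LpxC1 to 183 ± 66.7 against 24.4 ± 15.9 (log2 fold change 2.96 ± 0.48, adjusted p = 0.00818). IBM1 (AT3G07610, chromosome 3, 2425884 to 2433113), a histone demethylase gene, fell to 526 ± 12.5 against 730.1 ± 32.8 (log2 fold change -0.47 ± 0.08, adjusted p = 0.00386). FLC rose to 35.9 ± 3.19 against 8.03 ± 2.79 (log2 fold change 2.06 ± 0.40, adjusted p = 0.00851). In limma 760 genes higher and 1071 lower among 23740 tested were called, 115 and 346 at least 2-fold. The 1831 calls became 889 without atx4/5;jmj24 replicate 2, 1006 without Col-0 replicate 3 and 209 without a mean-variance trend, where the split was 61 up and 148 down. With equal column totals it was 1036 up and 928 down. 19 of the 30 called genes named by the rule kept their call without any 1 library and 7 under all other alternatives. Not among the 19 were AGL72, PDF1.2A, SOM, AGL58, CBL7, AOC2, JAZ2, FIT, 5MAT, UF3GT and FLC.

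Compared directly with jmj24 in the same set, atx4/5;jmj24 had 36 genes higher and 141 lower. HOL2 fell to 15.6 ± 7.66 against 96.4 ± 5.35 (log2 fold change -2.63 ± 0.29, adjusted p = 0.00251) and BAM6 to 16.2 ± 7.28 against 78.3 ± 2.35 (log2 fold change -2.27 ± 0.33, adjusted p = 0.0141). LpxC1 rose to 183 ± 66.7 against 17.7 ± 4.94 (log2 fold change 3.27 ± 0.48, adjusted p = 0.0252) and CRK23, a receptor-like kinase gene, to 20.7 ± 2.35 against 1.57 ± 0.778 (log2 fold change 3.11 ± 0.53, adjusted p = 0.0215). NUDT24 was at 29.3 ± 8.24 against 4.17 ± 1.59 and CALS5, a callose synthase gene, at 4.54 ± 2.09 against 28.1 ± 3.86. These 6 calls were each lost without at least 1 library. The count of 177 fell without any 1 library, most without jmj24 replicate 1. Without a mean-variance trend 25 were up and 48 down, and 12 of these 73 were among the 177. With only the 2 groups fitted 57 rose and 122 fell. The comparison with atx4/5 was not tested because its values lie in another set. Side by side, HOL2 was at 15.6 against 351 in Col-0 in atx4/5;jmj24 and at 26.4 against 526 in atx4/5.

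The libraries labelled atx1/2/4/5 differed from Col-0 in 33.3% of the tested genes. The jasmonate and salicylic acid lists were called higher, with 16 of 19 and 13 of 24 genes up, and the photosynthesis and auxin lists lower, with 20 of 21 and 13 of 19 genes down. These 4 calls were lost with an estimated correlation (adjusted p = 0.164 to 0.276), and that of the photosynthesis list also with quantile normalization (adjusted p = 0.262). The defensin genes PDF1.2A and PDF1.2c rose to 4076 ± 189 against 2.51 ± 2.2 (log2 fold change 10.34 ± 0.58, adjusted p = 1.32e-06) and 2111 ± 169 against 3.49 ± 0.592 (log2 fold change 8.88 ± 0.70, adjusted p = 2.31e-06). PR1 rose to 2341 ± 780.5 against 7.94 ± 5.4 (log2 fold change 8.14 ± 0.85, adjusted p = 1.89e-04) and NATA1 (AT2G39030), an acetyltransferase gene, to 4825 ± 1442 against 28.6 ± 12.9 (log2 fold change 7.39 ± 0.68, adjusted p = 1.13e-04). PDF1.2A, PDF1.2b, PDF1.2c and PDF1.3 are similar in sequence, as are the LHCB1 genes, so the values of single members are uncertain. The largest falls included those of the receptor kinase gene RKF1 (AT1G29750) to 14.5 ± 13.6 against 749 ± 44.5 (log2 fold change -5.94 ± 0.55, adjusted p = 1.25e-04) and SBT3.12 to 8.26 ± 11.2 against 290.5 ± 39.4 (log2 fold change -5.93 ± 0.98, adjusted p = 0.00221). RKF1 is the last of 4 neighbours on chromosome 1, between 10393659 and 10420774, that were each at least 4-fold lower in atx1/2/4/5. The serine racemase gene SR fell to 5.42 ± 7.66 against 127 ± 11.8, BAM6 to 9.85 ± 10.1 against 138 ± 22.8 and CHR42 (AT5G20420), which encodes a chromatin remodelling protein, to 1.66 ± 0.094 against 54.3 ± 13.1 (log2 fold change -4.36 ± 0.86).

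Among the lists in atx1/2/4/5, 16 of 19 jasmonate genes rose, 18 adjusted over the list alone (camera, adjusted p = 7.21e-13, adjusted p = 0.164 with an estimated correlation). LOX2 was at 58733 ± 2268 against 17158 ± 196 and AOC2 at 11219 ± 923 against 3172 ± 396. 13 of 24 salicylic acid and immune genes rose and 1 fell, 13 and 1 adjusted over the list alone (adjusted p = 3.07e-05, adjusted p = 0.169 with an estimated correlation). PR2 was at 1969 ± 90.6 against 60.7 ± 22.1 and WRKY18 at 635 ± 4.26 against 158 ± 6.94. 20 of 21 photosynthesis genes fell, 20 adjusted over the list alone (adjusted p = 7.21e-13, adjusted p = 0.276 with an estimated correlation), and this list call was lost with quantile normalization (adjusted p = 0.262). LHCB1.1 fell to 119046 ± 2090.5 against 202300.0 ± 4728 (log2 fold change -0.76 ± 0.05), a call that was also lost with quantile normalization. 13 of 19 auxin and elongation genes fell and 2 rose, 14 and 3 adjusted over the list alone (adjusted p = 1.09e-04, adjusted p = 0.169 with an estimated correlation). The growth regulator PIF4 was at 3251 ± 58.8 against 6049 ± 448. 8 of 11 flavonoid genes rose, 10 adjusted over the list alone (adjusted p = 1.01e-04, adjusted p = 0.333 with an estimated correlation). CHS was at 9988 ± 2607 against 4986 ± 69.2. 10 of 20 seed maturation genes rose and 2 fell (adjusted p = 0.00189, adjusted p = 0.333 with an estimated correlation). Higher calls were also made for DNA damage (5 of 11 up, adjusted p = 0.0145, adjusted p = 0.473 with an estimated correlation), heat shock (3 of 18 up, adjusted p = 0.00943, adjusted p = 0.462 with an estimated correlation) and shoot meristem genes (4 of 9 up, adjusted p = 0.025, adjusted p = 0.169 with an estimated correlation). These 3 calls were each lost without at least 1 library. Limma called 4025 genes higher and 4248 lower among 24843 tested, 949 and 983 at least 2-fold. With column totals set equal the split became 6506 up and 2892 down, with the median of all genes moved by 0.130 on the log2 scale. The call of the regulator PAP1 was lost without Col-0 replicate 1 or atx1/2/4/5 replicate 2, and 28 of the 29 called genes named by the rule kept theirs whichever library was left out.

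The libraries labelled atx2/3/4/5, in which ATX3 was higher and ATX2 not lower, gave the highest number of calls of the 9 comparisons with Col-0, with 4433 genes higher and 5000 lower among 24843 tested, 1132 and 1341 of them at least 2-fold. PDF1.2A rose to 3889 ± 1822 against 2.51 ± 2.2 (log2 fold change 10.19 ± 0.58, adjusted p = 8.38e-07) and the defence gene ELI3-2 to 739.9 ± 431 against 0.984 ± 1.38 (log2 fold change 8.61 ± 0.60, adjusted p = 3.57e-08). NATA1 rose to 9467 ± 874 against 28.6 ± 12.9 (log2 fold change 8.39 ± 0.68, adjusted p = 4.09e-05). The thionin gene THI2.1 was at 0 in both Col-0 libraries and at 363 ± 63 here, at least 121-fold higher. The largest falls included those of HOL2 to 18.5 ± 6.01 against 526 ± 3.66 (log2 fold change -4.79 ± 0.34, adjusted p = 5.3e-07) and TRFL8 to 8.19 ± 1.59 against 191 ± 28.5 (log2 fold change -4.39 ± 0.33, adjusted p = 7.94e-08). The seed dormancy gene DOG1 fell to 2.17 ± 1.32 against 57.9 ± 4.68 (log2 fold change -4.28 ± 0.39, adjusted p = 4.87e-07). 18 of 19 jasmonate genes rose, 18 adjusted over the list alone (camera, adjusted p = 4.04e-16, adjusted p = 0.0829 with an estimated correlation). VSP2 rose to 29402 ± 1095 against 7273 ± 229 and LOX2 to 77788 ± 516 against 17158 ± 196. 21 of 21 photosynthesis genes fell, 21 adjusted over the list alone (adjusted p = 2.76e-15, adjusted p = 0.177 with an estimated correlation). LHCA3 fell to 73079 ± 3555 against 146069 ± 5095. In the salicylic acid and immune list 14 of 24 rose and 1 fell, 15 and 1 adjusted over the list alone (adjusted p = 5.18e-08, adjusted p = 0.0829 with an estimated correlation). PR2 was at 3488 ± 291 against 60.7 ± 22.1 and the senescence gene SAG13 at 4422 ± 2200.3 against 62.4 ± 1.53. 15 of 19 auxin genes fell and 1 rose, 15 and 1 adjusted over the list alone (adjusted p = 4.84e-07, adjusted p = 0.0829 with an estimated correlation). IAA3 was at 376 ± 35.2 against 1187 ± 22.7. All 11 measured flavonoid genes rose, 11 adjusted over the list alone (adjusted p = 9.19e-07, adjusted p = 0.214 with an estimated correlation). PAP1 was at 256 ± 22.4 against 43.8 ± 9.9. 12 of 15 glucosinolate genes rose, 13 adjusted over the list alone (adjusted p = 1.04e-06, adjusted p = 0.177 with an estimated correlation). 8 of 11 DNA damage genes rose and 1 fell (adjusted p = 0.00135, adjusted p = 0.363 with an estimated correlation). Shoot meristem genes were called higher (2 of 9 up, adjusted p = 0.0444, adjusted p = 0.177 with an estimated correlation). Heat shock genes were called lower (9 of 18 down, adjusted p = 0.0164, adjusted p = 0.534 with an estimated correlation). Both calls were lost without atx2/3/4/5 replicate 1. With equal column totals 7979 genes rose and 3266 fell, the median of all genes having moved by 0.172. 30 of 30 called genes named by the rule kept their call whichever library was left out.

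**Figure D4:**
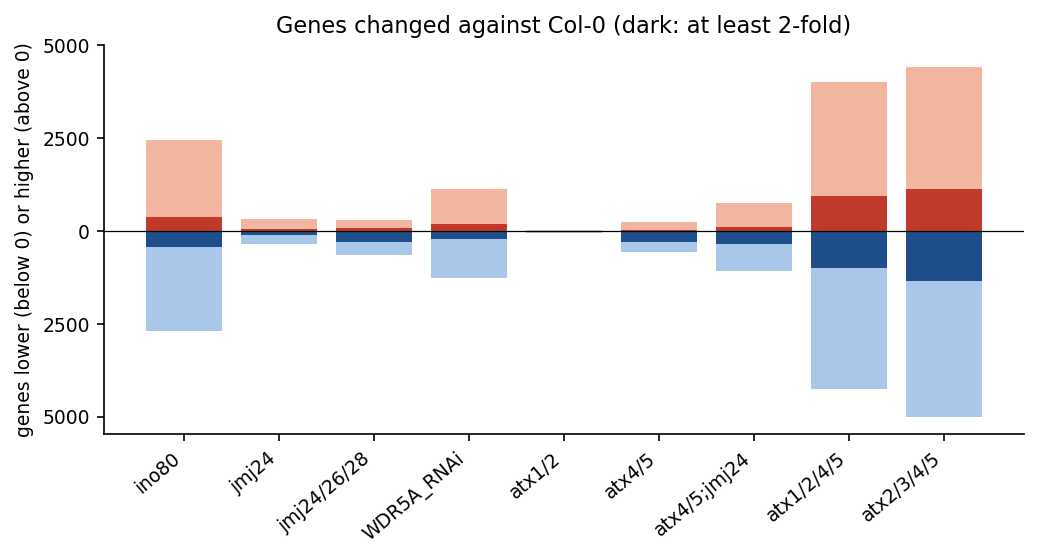
Number of genes higher (above 0) and lower (below 0) than Col-0 in each genotype (horizontal axis) at an adjusted p under 0.05 in limma, with genes changed at least 2-fold in dark colours. The bars run from 20 up and 50 down in atx1/2 to 4433 up and 5000 down in atx2/3/4/5.

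**Figure D5:**
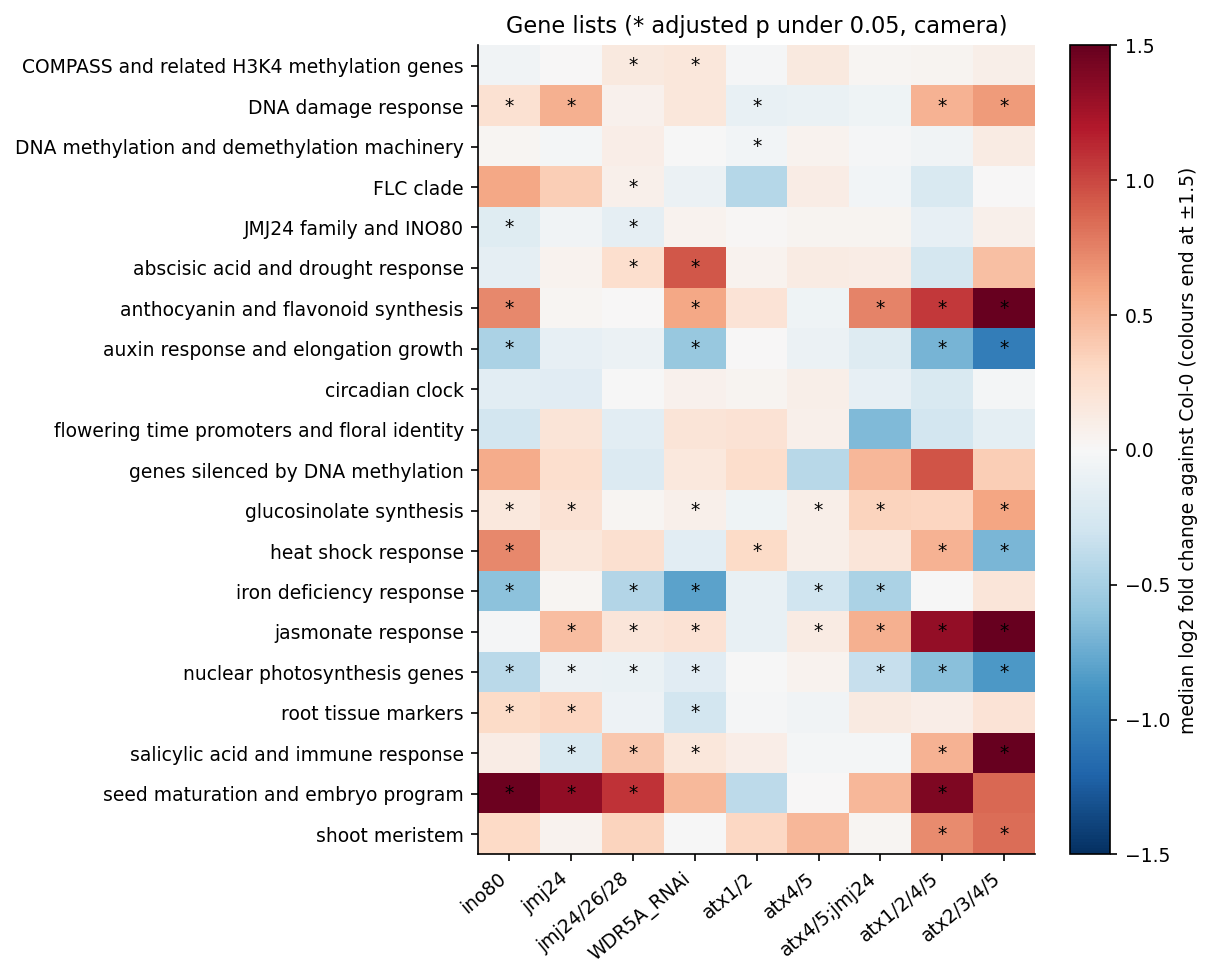
Median log2 fold change against Col-0 (colour, ending at ±1.5) of each of the 20 gene lists (rows) in each genotype (columns), with an asterisk where the camera test passed an adjusted p of 0.05. Photosynthesis genes are lowest in atx2/3/4/5 (-0.87) and atx1/2/4/5 (-0.63), where jasmonate genes are at 2.17 and 1.31.

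Direct comparisons within set 3 asked what the combination of 4 mutations adds. Against atx1/2, the libraries labelled atx1/2/4/5 had 3750 genes higher and 3944 lower, and against atx4/5 they had 4074 higher and 4235 lower. PDF1.2c, at 2111 ± 169 in atx1/2/4/5, was at 2.71 ± 2.32 in atx1/2 (log2 fold change 9.31 ± 0.70, adjusted p = 1.78e-06) and 1.19 ± 0.0222 in atx4/5 (log2 fold change 9.91 ± 0.70, adjusted p = 1e-06). PR1 was at 7.5 ± 1.14 in atx1/2 and 8.8 ± 10.2 in atx4/5, both lower than in atx1/2/4/5 (adjusted p = 2.09e-04 and adjusted p = 1.52e-04). RKF1, at 14.5 ± 13.6 in atx1/2/4/5, was at 508 ± 75.6 in atx1/2 and 817 ± 13.4 in atx4/5. SR fell against both (log2 fold change -5.02 ± 0.99 and log2 fold change -3.67 ± 0.99), although its call against atx4/5 was lost without either atx4/5 library. With equal column totals the splits became 6083 up and 2716 down against atx1/2, and 6675 up and 2592 down against atx4/5.

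The test of the interaction asked whether the effect of atx1/2/4/5 equals the sum of the effects of atx1/2 and atx4/5 on the log2 scale. It called 4498 genes, 2141 above the sum and 2357 below it, of which 637 and 413 differed at least 2-fold. Among the largest differences above the sum were those of PDF1.2c (log2 difference 10.33 ± 0.99, adjusted p = 4.69e-05), PDF1.2b (8.47 ± 0.87, adjusted p = 1.52e-05) and PR1 (8.36 ± 1.21, adjusted p = 0.00252). Among the largest below it were those of RKF1 (-5.50 ± 0.78, adjusted p = 0.00272), which lies in a run of lowered neighbours, the terpene synthase gene TPS14 (-3.66 ± 0.82, adjusted p = 0.00553) and GDPD3 (-3.58 ± 1.1, adjusted p = 0.0425). GDPD3 lost its call without any 1 library of Col-0, atx1/2 or atx4/5. Of the 8273 genes called in atx1/2/4/5, 7714 were called in neither atx1/2 nor atx4/5. With equal column totals 3736 genes lay above and 1493 below the sum. The non-additive effect in atx4/5;jmj24 was not tested, since its parts lie in 2 sets.

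The 2 combinations of 4 mutations were also set against each other. The libraries labelled atx1/2/4/5 had 2195 genes higher and 1679 lower than those labelled atx2/3/4/5. Of the genes with a symbol that met the naming rule, the 3 with the largest rises were microRNA genes. MIR168a was at 174 ± 37.4 against 11 ± 2.34 (log2 fold change 3.86 ± 0.32, adjusted p = 2.02e-06). MIR846 was at 20.7 ± 8.15 against 0.568 ± 0.797 (log2 fold change 3.83 ± 0.63) and MIR393b at 19.6 ± 6 against 0.526 ± 0.716 (log2 fold change 3.81 ± 0.50). RKF1 was lower, at 14.5 ± 13.6 against 444 ± 9.13 (log2 fold change -5.19 ± 0.55, adjusted p = 8.57e-04). Also lower were THI2.1 at 13.7 ± 8.89 against 363 ± 63 (log2 fold change -4.76 ± 0.57, adjusted p = 5.22e-05) and the Argonaute gene AGO5 at 2.07 ± 1.81 against 22.4 ± 1.99 (log2 fold change -3.07 ± 0.62, adjusted p = 0.00329). The total of 3874 was 2247 without atx1/2/4/5 replicate 1, 2243 without atx1/2/4/5 replicate 2, 2140 without atx2/3/4/5 replicate 1, 2079 without atx2/3/4/5 replicate 2 and 2499 without a mean-variance trend. With equal column totals 1722 genes were higher and 2132 lower. The calls against Col-0 overlapped widely. 2839 genes were higher and 3101 lower in both, where independent lists of these sizes would share 718 and 855, and 74 genes were called in opposite directions. Unchanged groups simulated against the same Col-0 libraries shared 0.05 calls on average. Few genes pass the threshold where no group differs, so this number does not measure what changed groups share through their controls. The fold changes correlated over genes, which are not independent replicates, at 0.747 against 0.504 in the simulation, and their covariance was 0.473 against 0.0625. A split of the 2 Col-0 libraries would leave 1 for each mutant and was not made, so part of the excess can come from the shared controls.

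Overlaps were counted for all 36 pairs of mutants, 16 with shared and 20 with separate Col-0 libraries. With separate Col-0 libraries, ino80 and jmj24 shared 170 higher and 190 lower genes, where independent lists would share 35.8 and 40.1, with 31 called in opposite directions. Likewise ino80 and atx1/2/4/5 shared 1250 higher and 1510 lower genes, where independent lists would share 418 and 497, with 282 opposite. The pair jmj24 and jmj24/26/28 shared 65 higher and 136 lower genes, where independent lists would share 4.37 and 9.17, and atx4/5;jmj24 and atx4/5 shared 55 higher and 263 lower genes, where independent lists would share 7.71 and 25.4, with 10 and 18 opposite. In these 4 pairs the fold changes correlated at 0.294, 0.351, 0.332 and 0.39 over genes. With shared Col-0 libraries, atx4/5 and jmj24/26/28 had in common 84 higher and 232 lower genes, where independent lists would share 3.02 and 14.6, with a covariance of 0.162 against a simulated 0.0621. In set 2, jmj24 and atx4/5;jmj24 had in common 239 higher and 264 lower genes, where independent lists would share 10.6 and 15.3. Their covariance was 0.175 against a simulated 0.0678. Unchanged groups shared 2 genes in the simulation, which does not measure what changed groups share through their controls. These 2 pairs had 5 and 3 genes called in opposite directions. Other pairs with separate Col-0 libraries agreed less. In ino80 and WDR5A_RNAi 298 genes were called in opposite directions against 231 higher and 271 lower in both, where independent lists would share 118 and 146.5. The fold changes correlated at 0.103. In jmj24 and WDR5A_RNAi these were 41 against 39 and 47 (0.0934), where independent lists would share 15.5 and 17.95. In ino80 and atx1/2 they were 17 against 2 and 7 (-0.032), where independent lists would share 2.04 and 5.89. No gene was called in the same direction in all 9 comparisons at an adjusted p under 0.05 in limma. In 8 of them, 5 genes were higher (AT1G17160, MLP168, ETT, CRR6 and VGT1) and 14 lower, among them AT1G64795, HOL2 and TRFL8.

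The series title also concerns DNA methylation, which was not measured. The DNA methylation and demethylation machinery had 38 or 39 measured genes. Of these, 3 rose and 3 fell in ino80, 4 and 6 in atx1/2/4/5 and 8 and 5 in atx2/3/4/5. The list was called in atx1/2 alone (0 of 39 past the threshold, adjusted p = 0.0144). That call was lost with an estimated correlation (adjusted p = 0.508) and without Col-0 replicate 2 or atx1/2 replicate 1. IDN2, FDM2 and QQS were among 59 genes lower in at least 7 of the 9 genotypes. IBM1 passed the test in atx4/5;jmj24 alone, a call lost without a mean-variance trend. It lay at 83.4% to 97.5% of Col-0 in the other 8 comparisons. Genes silenced by DNA methylation were not called as a list in any comparison, with 3 or 4 measured, of which 2 rose and 1 fell in atx1/2/4/5 and likewise in atx2/3/4/5. FLC passed the test in ino80, jmj24, atx4/5;jmj24 and jmj24/26/28, all 4 higher, with the call kept whichever library was left out in jmj24/26/28 alone. FT, the mobile flowering signal, passed it in none of the 9. FT lay at 58.7 ± 14.5 in the Col-0 libraries of set 2 and at 7.24 ± 1.54 and 6.53 ± 5.15 in those of sets 1 and 3, which were normalised separately. Flowering promoters and floral identity genes were not called as a list in any comparison, with 5 of 20 up and 4 down in atx1/2/4/5. Circadian clock genes were not called either, with 3 up and 9 down of 19 in atx1/2/4/5 and 2 up and 6 down in ino80.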

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

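Of the tests below, those of the scaling and of 1 unusual library were chosen after the result was seen. A difference between groups was flagged in set 3. The effect of the atx4 and atx5 mutations, as labelled, differed with and without the atx1 and atx2 mutations. Tested directly as the non-additive term, it differed in 4498 genes. The named genes flagged with it were PDF1.2c at a log2 difference of 10.33, PDF1.2b at 8.47, PR1 at 8.36, RKF1 at -5.50, TPS14 at -3.66 and GDPD3 at -3.58. A test for 1 library far from the other Col-0 libraries found none in 14 levels. It cannot find a set whose 2 Col-0 libraries depart together, as with FT at 58.7 ± 14.5 in set 2 and at 7.24 ± 1.54 and 6.53 ± 5.15 in sets 1 and 3.

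The tables argue against 3 technical explanations of the non-additive response as a whole. The authors' scaling is not the whole cause, since 80.8% of the genes kept their call with equal column totals and 91.8% with quantile normalization, although the first moved the share of genes above the sum. A single unusual library is not the cause either, since at least 3150 genes were called without any 1 library, 70.0% of the count. A floor of the log scale, at which 2 falls cannot add up, would raise genes above the sum, but only 3.13% of those above it had summed effects below 0 reads. What stays open is redundancy among the ATX genes, as a hypothesis found and tested on the same libraries, and a difference in growth stage or health of the atx1/2/4/5 seedlings, for which no test was run. In atx1/2, ATX2 was not called lower, and ATX1 was at 181 and 180.5 against 258.4 and 256.7 in Col-0 without passing the test (adjusted p = 0.921, and 0.11 without replicate 1 of atx1/2/4/5). The part of the atx1 and atx2 mutations therefore rests in part on the labels. The test also takes the loss of ATX4 and ATX5 as equal in atx4/5 and atx1/2/4/5. ATX5 was at 237.2 and 223.7 in atx4/5 but at 43.8 and 31.9 in atx1/2/4/5. A deeper loss of ATX5 in atx1/2/4/5 therefore stays open as well, and its part was not tested.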

How the results depend on the processing

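Column totals set equal, quantile normalization for the lists and 1 further fit of ATX1 were chosen after seeing the data. Of 3007 values of named genes under the alternatives, 2569 kept their direction and their side of the threshold, 416 no longer passed it, 5 newly passed it and 17 changed sign, none of them for a gene called in the main analysis. The genes named for the largest changes against Col-0 had both mutant libraries on the same side of both Col-0 libraries. Leaving out a library could therefore not change their sign. Where a library is left out, the lone library of its group is assumed to vary like the others, and counts fall with fewer libraries.

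Without 1 library, the genes changed against Col-0 numbered 400 to 3206 in ino80, 178 to 459 in jmj24, 889 to 1412 in atx4/5;jmj24, 18 to 44 in atx1/2, 361 to 455 in atx4/5, 5813 to 6602 in atx1/2/4/5, 7102 to 7663 in atx2/3/4/5, 396 to 723 in jmj24/26/28 and 710 to 1806 in WDR5A_RNAi. For atx1/2/4/5 they numbered 5241 to 6153 against atx1/2, 5851 to 6796 against atx4/5 and 2079 to 2247 against atx2/3/4/5. They numbered 34 to 175 for atx4/5;jmj24 against jmj24 and 3150 to 3997 for the non-additive test. Called lists numbered 7 to 10 in ino80, 6 to 8 in jmj24, 4 to 8 in atx4/5;jmj24, 2 to 11 in atx1/2, 0 to 5 in atx4/5, 6 to 11 in atx1/2/4/5, 8 to 11 in atx2/3/4/5, 7 to 13 in jmj24/26/28 and 8 to 9 in WDR5A_RNAi.

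For the changes that follow, the cause was not tested. In limma without a mean-variance trend the counts were 581 in ino80, 77 in jmj24, 209 in atx4/5;jmj24, 416 in atx4/5, 476 in jmj24/26/28, 1233 in WDR5A_RNAi, 2499 for atx1/2/4/5 against atx2/3/4/5 and 73 for atx4/5;jmj24 against jmj24. With only the groups compared in the fit they were 33 in atx1/2, 468 in atx4/5 and 1222 in WDR5A_RNAi. With an estimated inter-gene correlation 0 lists were called in each comparison with Col-0. With fry in place of camera, 5 lists were called in ino80, 0 in atx1/2, 0 in atx4/5, 14 in atx1/2/4/5 and 6 in WDR5A_RNAi. With equal column totals 5 lists were called in atx1/2. At an adjusted p under 0.01, genes called in the same direction numbered 129 in ino80 and jmj24, 1383 in ino80 and atx1/2/4/5, 201 in jmj24 and atx4/5;jmj24, 81 in jmj24 and jmj24/26/28, 141 in atx4/5;jmj24 and atx4/5, 124 in atx4/5 and jmj24/26/28, 103 in ino80 and WDR5A_RNAi, 14 in jmj24 and WDR5A_RNAi, 2 in ino80 and atx1/2 and 3920 in atx1/2/4/5 and atx2/3/4/5.

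The values that changed sign were all log2 fold changes of genes not called. FT (AT1G65480) was at 0.0061 in jmj24 and 0.013 in atx4/5;jmj24 without Col-0 replicate 3 (lowest -0.494 and -0.487). In atx1/2 it was at -0.70 without Col-0 replicate 2 and -0.0069 without atx1/2 replicate 1 (highest 0.82). In atx4/5 it was at 0.35 with quantile normalization, 0.69 without Col-0 replicate 1 and 0.073 without atx4/5 replicate 1 (lowest -0.83). ATX2 was at 0.047 in atx1/2 without Col-0 replicate 2 (lowest -0.083), and without Col-0 replicate 1 at -0.030 in atx1/2/4/5 and -0.041 in atx2/3/4/5 (highest 0.10 and 0.089). FLC in atx1/2/4/5 was at 0.17 without Col-0 replicate 2 and 0.34 without atx1/2/4/5 replicate 2 (lowest -0.72). IBM1 in atx1/2/4/5 was at 0.015 without Col-0 replicate 2, 0.028 without atx1/2/4/5 replicate 2 (lowest -0.10) and 0.10 with equal column totals, and in atx2/3/4/5 at 0.044 with equal column totals. ATX1 in atx1/2/4/5 was at -0.43 without replicate 1 (adjusted p = 0.0366) and at most 1.14, without replicate 2 (adjusted p = 4.73e-05), so it passed the test in opposite directions. In atx1/2 it was at -0.51 ± 0.40 (adjusted p = 0.921), and at -0.51 ± 0.12 (adjusted p = 0.11) without replicate 1 of atx1/2/4/5.

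No label ties the replicate numbers to a batch. Correlations of same-number deviations were -0.005 to 0.108 over the 22 pairs of groups with the same numbers, 2 of them over 0.1. In set 3, however, replicate 1 lay above replicate 2 on the second principal component in 7 of 7 groups. The lower number also lay above the higher in 2 of 2 groups of set 1 and 3 of 3 of set 2. An effect shared by replicate number can therefore not be excluded, and the main fits hold no term for it. No paired analysis was possible for ino80, jmj24 and atx4/5;jmj24 against Col-0 because their Col-0 libraries have other numbers. With the replicate number as a block, the counts rose to 108 from 70 in atx1/2, 1357 from 804 in atx4/5, 1624 from 956 in jmj24/26/28 and 3565 from 2374 in WDR5A_RNAi, and 8 lists were called in atx1/2. For atx4/5;jmj24 against jmj24, the block, fitted with these 2 groups alone, gave 97 genes up and 136 down in place of 36 and 141. It shared 111 calls with the 177, and CRK23, NUDT24, CALS5 and BAM6 were not called with it. The alternatives for raw counts, edgeR with other size factors and the DESeq2 test, were not run, since the values are not counts. Depth limits the genes at low levels, where 1 read is worth 0.808 to 1.198.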

Other observations

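In the direct comparison of the 2 combinations of 4 mutations, 30 of 142 measured microRNA genes were higher and 4 lower in the libraries labelled atx1/2/4/5, and 32 and 4 with quantile normalization. Of all 24843 tested genes 15.59% were called in it. Against Col-0, 32 microRNA genes were higher and 6 lower in atx1/2/4/5, where 33.3% of all genes were called, and 4 higher and 14 lower in atx2/3/4/5, where 37.97% were called. The class was chosen after its values were seen, and its enrichment was not tested. These genes often overlap others, and the strand of the libraries is not stated, so the assignment of their reads is uncertain.

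Some genes were close to absent in several genotypes. AT1G64795 lay between 81.9 and 189.7 in the 6 Col-0 libraries, at 142.7 and 145 in the libraries labelled WDR5A_RNAi, and between 0 and 7.3 in all other mutant libraries. AT1G75945 was at 110.3 and 114.2 in the Col-0 libraries of set 3, at 1.03 and 0.01 in atx1/2, 2.49 and 1.98 in jmj24/26/28, 4.79 and 8.22 in atx4/5, 10.27 and 14.77 in atx1/2/4/5, 72.7 and 86.8 in atx2/3/4/5 and 135.6 and 150.5 in WDR5A_RNAi. In jmj24 it was at 118.5 and 129.7 and in atx4/5;jmj24 at 162.5 and 125.2 against 169.8 and 150.3, and in ino80 at 164.6 and 162.7 against 213.9 and 221.8. The neighbours AT1G29720, AT1G29730 and AT1G29740 on chromosome 1, between 10393659 and 10413119, were at least 4-fold lower in atx1/2, atx1/2/4/5 and jmj24/26/28. In atx1/2/4/5 the run also held RKF1 and ended at 10420774. Similar runs of 3 genes lay on chromosome 3 in atx1/2/4/5 (AT3G52526 to AT3G52535 and AT3G62499 to AT3G62510) and in atx2/3/4/5 (AT3G21310 to AT3G21330). QQS was at 36.9 and 55.7 in the Col-0 libraries of set 3 and at 788.9 and 652.5 in those of set 2.

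In the 2 patterns that follow, the tests of the unusual Col-0 libraries, of reads that cannot be placed and of a structural change were chosen after the result was seen. ATX4 and ATX5 were higher in jmj24, jmj24/26/28 and ino80, where neither is mutated. The authors' scaling is not the cause, since the smallest of the 6 log2 fold changes under quantile normalization and equal column totals was 0.674. Reads shared between ATX4 and ATX5 are not the cause either, with 0% of their 50-base windows shared. Both genes were called in 3 sets with separate Col-0 libraries. The pattern was chosen for these calls, so they cannot decide whether an unusual pair of Col-0 libraries is a cause. A rise of ATX4 and ATX5 when JMJ24 or INO80 is lost stays open as a biological hypothesis, found and tested on the same data, and its calls are fragile. Without a mean-variance trend ATX4 in ino80 alone was called (adjusted p = 0.0466), and the other 5 adjusted p were 0.0521 to 0.153. The ATX5 call was also lost in jmj24/26/28 without Col-0 replicate 1 (adjusted p = 0.108), replicate 1 (adjusted p = 0.0664) or replicate 2 (adjusted p = 0.0659) of the mutant, and in ino80 without replicate 1 (adjusted p = 0.081) or replicate 2 (adjusted p = 0.0605) of the mutant. The log2 fold changes in these fits were 0.591 to 1.245. The rise is also not confined to those genotypes. In the libraries labelled WDR5A_RNAi, where JMJ24 and INO80 were not called, ATX5 was called higher (log2 fold change 0.45 ± 0.14, adjusted p = 0.0491), a call lost without any 1 of the 4 libraries. ATX4 was at 695 ± 43.1 against 500.2 ± 3.3 there without a call (adjusted p = 0.18).

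RK3, B120, CRK28 and CRK29 span 16409 bases that begin 2568 bases from JMJ28, and were at 0 in both jmj24/26/28 libraries. Reads that cannot be placed on these genes do not explain this, since the lowest value of the 4 genes in the other 12 libraries of the set was 87.5. Nor do genes lowered one by one that lie together by chance, since 0 of 1000 shuffles of the gene order gave such a run. A structural change linked to the jmj28 allele, such as a deletion, stays open and undecided. The number of expressed genes at their Col-0 level between JMJ28 and the 4 genes was 0, but no annotated gene lies there, so that count decides nothing. Reads or DNA across the site would be needed. In jmj24, which has no jmj28 mutation, the 4 genes were at 68.9, 218.5, 256.5 and 1185 against 167.1, 151.6, 230.9 and 794.2 in the Col-0 libraries of its set, and no biological explanation was tested.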
